A study of Mus musculus with 6 samples.

How the data were processed

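Total RNA from the apex of mouse hearts was hybridised to Affymetrix arrays after extraction with Trizol and RNeasy columns, per the labels' protocols. The series holds 6 arrays, 1 per heart: 3 hearts without Cre (no_Cre 1 to 3) and 3 hearts with αMHC-Cre (aMHC_Cre 1 to 3). The titles call them biological replicates. The authors deposited 1 log2 value per probe set and array. The values come from PLIER, a method that combines the probes of a probe set into 1 signal, per the submitters' processing notes. Its settings, the background correction and any normalization between arrays are not given in the sources used here. Base 2 is inferred from the deposited values, whose maximum per array is 13.97 to 14.00, and each array holds 749 to 902 values below 0, which shows that no offset keeps low signals positive. Such low values make differences of dim probe sets large and unsteady. No detection calls were used here, so no probe set is called absent. No pooled columns and no other columns were found in the table.

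The table lists 45101 probe sets. Left out were 64 control probe sets and the 40% of the others with the lowest mean over the 6 arrays (18015, mean under 5.16), which leaves 27022. A rule set beforehand asked for no further normalization where array medians differ by at most 0.1, and they ranged from 5.72 to 5.81. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), without covariates, and p-values were adjusted by Benjamini-Hochberg over the tested probe sets at a threshold of 0.05. Zfpm2 was judged in the same fit run on all probe sets except controls, as fixed beforehand. Genes take the adjusted p of the probe set that stands for them.

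Gene names came from the platform annotation supplied with the table: 34945 probe sets carry 1 gene symbol, 932 several and 9160 none, and only those with 1 were named. Of these, 34741 were found by Entrez number in a RefSeq gene table of assembly GRCm38.p6, used for names and gene order only, and 0 symbols needed an update. A gene was represented by its probe set with the highest mean, and 13062 genes were tested. Genome positions of probe sets were not used here.

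Before the data were examined, 26 lists of genes were fixed for cardiac functions and for cell types of the apex, with a short list of sex-linked genes for values only. Lists were tested with camera (preset correlation 0.01, against all other genes), with an estimated correlation and with fry, each adjusted over the 26 lists. Only 3 genes stand in more than 1 list. Members too dim or not named in the annotation were not tested. Named genes follow a rule fixed at the same time: the 12 genes with the highest and the 12 with the lowest difference among those past the threshold whose groups do not overlap, without clone names, then up to 4 members past the threshold per list, or up to 2 as values if none passes. Genes outside this rule are said to have been chosen after their values were seen, except members that only complete a count. Of the 12 lowest genes, 1 is not reported here.

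Alternatives fixed beforehand were quantile normalization, median centring, no filter and a 60% filter, trend and robust variance settings, array weights, the replicate number as a block, other ways to represent a gene, other thresholds and leaving out each heart. Planned pseudocounts of 1 and 64 were meant for a linear table and did not apply. In their place, 1, 16 or 64 was added to the unlogged signal, and 2 settings without a filter were combined with other choices, all chosen after seeing the data. Array quality was compared with exact permutation tests. The procedure was tested on simulated data for this comparison, with normal noise and 27022 probe sets tested. The size of the noise came from the variances after eBayes, which draws them together across probe sets, so real variances differ more. The noise was drawn separately for each probe set, so correlation between genes was not simulated. In these data 200 probe sets were changed, and genes of the list of respiratory chain subunits were shifted by 0.5. Among changed probe sets that passed the filter, the procedure recovered 86.5% of the changes of 2-fold and 97.6% of those of 4-fold. Changes lost to the filter are not counted in these shares. Of its 180 calls, 10 were false. The shifted list had a camera adjusted p of 8.6e-43, and of 0.0025 with an estimated correlation, in data without correlation between genes.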

Results

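Gene expression was measured in the apex of 6 hearts from male mice aged 6 to 7 weeks, with 1 Affymetrix array per heart. Every animal carried 1 floxed allele and 1 deleted (delta) allele of Fog2, the gene with the official symbol Zfpm2, whose protein is a cofactor of GATA transcription factors. In 3 hearts an αMHC-Cre transgene was present, which produces Cre recombinase in cardiomyocytes and so can remove the floxed segment there. The other 3 hearts lacked Cre. They kept the floxed allele but also carried the deleted one, so they were not wild type. The comparison of these groups asks which transcripts of the adult heart differ when αMHC-Cre, which can delete Fog2 in cardiomyocytes, is present. No heart had Cre without a floxed allele, so effects of Cre itself and of the deletion cannot be told apart for any gene below. Each value is the log2 signal of a probe set, a group of probes for 1 transcript, and differences are hearts with Cre minus hearts without Cre.

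The array medians lay between 5.72 and 5.81 on the log2 scale. Across the tested probe sets, which are not independent replicates, pairs of arrays within a group correlated at 0.980 to 0.987 and pairs between groups at 0.964 to 0.973. The first principal component held 49.5% of the variance, with the hearts without Cre at -32.8 to -27.7 and those with Cre at 27.0 to 32.1. Of 6 array measures compared, 2 that can reflect RNA quality separated the groups without overlap, but in opposite directions. The 3' minus 5' signal of Actb was 0.35 ± 0.06 (SD, n = 3) without Cre and 0.27 ± 0.02 with Cre, and that of Gapdh was -0.11 ± 0.03 and -0.06 ± 0.01. In a two-sided exact permutation test each gave p = 0.1 (0.3 after Benjamini-Hochberg adjustment), the smallest value that 3 hearts against 3 allow.

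In hearts with Cre, 7 of 14 ventricular stress genes, 22 of 28 extracellular matrix genes and 7 of 18 interferon-stimulated genes rose, and 5 of 31 fatty acid oxidation genes fell. These 4 lists were called by camera, and all lost the call with an estimated correlation (adjusted p = 0.27 for the first 3 and 0.46 for the last). Nppb, which encodes B-type natriuretic peptide, rose by 3.61 ± 0.60 (SE) on the log2 scale (2.72 without no_Cre 2). Myh7, the β-myosin heavy chain, rose by 2.93 ± 0.14. Myl7, the myosin regulatory light chain typical of atria, went from 3.72 ± 0.54 (SD, n = 3) to 11.02 ± 0.36. Kcnip2, a subunit of the transient outward potassium channel, fell by 2.10 ± 0.22 (SE) on the log2 scale, while Kcne1, a subunit of the slow delayed rectifier, rose by 4.27 ± 0.25.

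The deleted gene was represented by 2 probe sets, which moved in opposite directions. The dimmer one read 6.34, 6.40 and 6.65 in the hearts without Cre and 5.46, 5.61 and 5.66 in those with Cre, a difference of -0.88 ± 0.13 (SE). The brighter one read 8.86, 8.83 and 8.96 without Cre and 10.71, 10.48 and 10.50 with Cre, and rose by 1.68 ± 0.11. In the limma fit of all probe sets chosen beforehand for Zfpm2, the adjusted p was 0.068 for the dimmer one, which does not pass, and 0.014 for the brighter one. In the fit without dim probe sets, used for all other genes, the adjusted p was 0.0052 and 0.00014. In the fit of all probe sets, the call of the brighter one was lost when any single heart was left out (adjusted p 0.051 to 0.070). Without dim probe sets, both were called whichever heart was left out. Which part of the gene each probe set measures is not given in the sources used here, so neither value by itself checks the deletion.

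Of 27022 tested probe sets, 1412 changed (limma, adjusted p under 0.05), 928 of them higher and 484 lower with Cre. Counted as genes, each through its brightest probe set, 815 of 13062 changed, with 549 higher and 266 lower. At least 2-fold changes were found for 235 genes in the upward and 54 in the downward direction, and at least 4-fold changes for 53 and 4. The groups did not overlap for 23.5% of the tested probe sets, against 10% by chance. Without a filter on dim probe sets the count was 275 probe sets, and 22 of the 67 named genes that changed kept their call. Leaving out 1 heart gave 913 without no_Cre 1, 923 without aMHC_Cre 1, 600 without aMHC_Cre 2 and 905 without aMHC_Cre 3. Counted as genes, 360 changed without aMHC_Cre 2 (74 of them lower) and 152 without a filter (22 lower).

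The genes that rose most were Spink4, a Kazal-type protease inhibitor, by 7.69 ± 0.46 (SE) on the log2 scale and Myl7 by 7.30 ± 0.27. They were followed by Plppr5, a lipid phosphatase-related membrane protein, at 5.32, the aquaporin Aqp6 at 4.89, the neurofilament chain Nefm at 4.82 and the anoctamin Ano3 at 4.43. Next came Kcne1 at 4.27, the replication kinase Cdc7 at 3.85, the germ cell RNA-binding protein Dazl at 3.75, Pgap1 at 3.63, Nppb at 3.61 and the Wnt inhibitor Sost at 3.45. Their adjusted p lay between 6.4e-06 for Myl7 and 0.010 for Nppb. Of these 12 genes, Spink4, Myl7, Plppr5, Aqp6, Nefm, Ano3, Cdc7, Dazl and Sost had a mean under 4.5 without Cre, where sizes and their order depend on the low end of the scale. With 16 added to the unlogged signal of the same probe sets, the differences were 6.73 for Spink4, 6.15 for Myl7, 4.02 for Plppr5, 3.94 for Kcne1, 3.86 for Aqp6 and 3.77 for Nefm, then 3.56 for Nppb, 3.40 for Pgap1, 3.16 for Ano3, 3.00 for Cdc7, 2.54 for Dazl and 2.49 for Sost. With 64 added, Dazl differed by 1.43 and Sost by 1.48. The spread of Nppb came from a single heart, no_Cre 2, at 7.76 against 10.58 and 10.29 in the others of its group, and without it the difference was 2.72. Nppb lost its call with trend and robust variance settings (adjusted p 0.12) and without aMHC_Cre 2 (0.058). Another tested probe set of Aqp6, with a mean of only 1.81 without Cre, differed by 8.28 (adjusted p 4.8e-05), and others differed by 6.13 for Plppr5, 3.52 for Pgap1, 3.12 for Kcne1 and 2.84 for Cdc7. Another tested probe set of Sost differed by -0.12 (adjusted p 0.69).

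The genes that fell most were Ano10, of the anoctamin family, by -2.24 ± 0.32 (SE) on the log2 scale, Kcnip2 by -2.10 and Mylk4, a myosin light chain kinase, by -1.95. Kcnv2, a silent potassium channel subunit, followed at -1.88, with Tbc1d10c at -1.83, the cAMP phosphodiesterase Pde7a at -1.74 and the tropomodulin Tmod4 at -1.72. Armh4 at -1.70, the splicing factor Rbfox1 at -1.67, the R-spondin receptor Lgr6 at -1.61 and the matrix protein Egflam at -1.60 came next. Adjusted p ran from 0.00039 for Rbfox1 to 0.010 for Kcnv2. All 7 tested probe sets of Pde7a fell, by -1.45 to -1.74, and all 4 of Rbfox1, by -1.48 to -1.74. Ano10 lost its call with trend and robust variance settings (adjusted p 0.052).

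**Figure D1:**
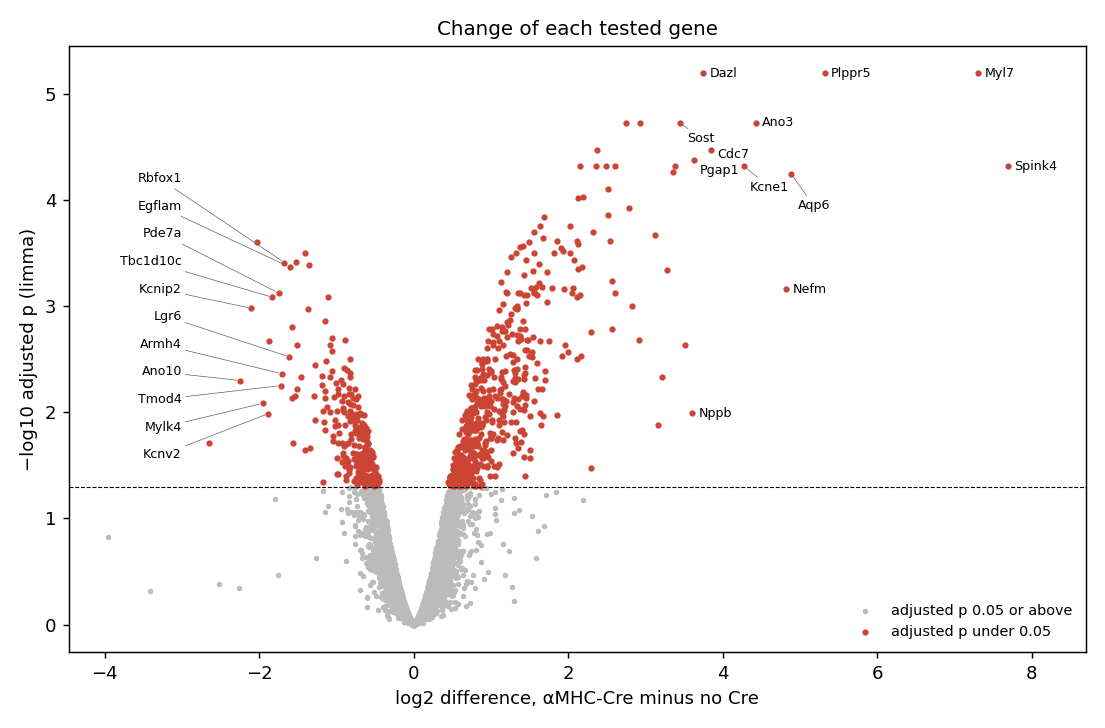
Each point is 1 of the 13062 tested genes, with the log2 difference between hearts with and without Cre on the horizontal axis and -log10 of the limma adjusted p on the vertical axis. The dashed line marks an adjusted p of 0.05, red points lie beyond it (549 higher, 266 lower), and the labelled genes are those named in the text as having risen or fallen most.

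Of 14 tested genes of the fetal and haemodynamic stress list, 7 rose and 0 fell (8 rose when adjusted over the list alone), with a median difference of 1.18. Myh7 went from 8.34 ± 0.19 (SD, n = 3) to 11.27 ± 0.15, Nppa, the atrial natriuretic peptide gene, from 11.67 ± 0.35 to 13.70 ± 0.02, and Acta1, skeletal α-actin, rose by 2.30 ± 0.27 (SE). Nppa with Cre lay near the array maxima of 13.97 to 14.00, so its rise may be compressed. The other members that rose were Mybpc2, Tnfrsf12a, Nppb and Rcan1. Ankrd1, singled out after its values had been seen, differed by 1.84 ± 0.46 without passing (adjusted p 0.056). Without no_Cre 2 it differed by 1.17 and passed (adjusted p 0.0031), and it also passed without no_Cre 1 (0.038) or no_Cre 3 (0.0496). The call of Rcan1 was lost whichever heart was left out (adjusted p 0.061 to 0.13). The list was shifted upward by camera (adjusted p 5.7e-07), a call that was lost with an estimated correlation (adjusted p = 0.27).

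Among extracellular matrix genes, 22 of 28 rose and 0 fell (25 adjusted over the list alone), with a median difference of 1.15. Col14a1 rose by 2.38 ± 0.13 (SE), the fibrillar collagen chain Col1a2 by 1.28 ± 0.15, the proteoglycan gene Bgn by 1.19 ± 0.14 and Timp1, an inhibitor of matrix metalloproteinases, by 1.75 ± 0.21. The camera adjusted p was 7.8e-23, and the adjusted p = 0.27 with an estimated correlation. Fibroblast markers moved in the same direction by less, with 3 of 15 higher (6 adjusted over the list alone) and a median of 0.33. Lum rose by 0.74 ± 0.12 and Mfap5 by 1.02 ± 0.18, and Dpt by 0.55 ± 0.13. The fibroblast list had a camera adjusted p of 0.00021, and adjusted p = 0.27 with an estimated correlation. The call of Dpt was lost whichever heart was left out (adjusted p 0.068 to 0.15), and that of Mfap5 without aMHC_Cre 2 (0.063).

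Interferon-stimulated genes were higher with Cre in 7 of 18 cases and lower in 0 (10 higher adjusted over the list alone), with a median of 0.59. Ifit1 rose by 1.91 ± 0.16 (SE), Usp18 and Ifit2 each by 0.88 ± 0.16 and the transcription factor Irf7 by 0.79 ± 0.13. The camera adjusted p was 1.3e-07, and the adjusted p = 0.27 with an estimated correlation.

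Among calcium handling, ion channel and gap junction genes, 3 of 31 rose and 4 fell (7 and 6 adjusted over the list alone), and the list as a whole was not shifted (camera adjusted p 0.76). Its median was -0.04 and its mean 0.03, and camera put it downward but fry upward. Kcne1 went from 5.94 ± 0.59 (SD, n = 3) to 10.21 ± 0.07, and Kcnq1, the channel that Kcne1 modulates, rose by 0.69 ± 0.12 (SE). Kcnj5, a subunit of the acetylcholine-activated potassium channel, rose by 1.11 ± 0.13. Kcnip2 went from 10.87 ± 0.07 (SD, n = 3) to 8.78 ± 0.51, and the transient outward channel genes Kcnd3 and Kcnd2 fell by 0.94 ± 0.13 (SE) and 0.77 ± 0.15. Kcnv2 fell by 1.88 ± 0.32. Of the other 2 tested probe sets of Kcnip2, 1 differed by -2.33 (adjusted p 0.00020) and 1 by -0.23 (0.51). Another tested probe set of Kcnd3 differed by 0.02 (adjusted p 0.97), and the call of this gene was lost in the mean over its probe sets (adjusted p 0.080). Kcnq1 and Kcnd2 were singled out after their values had been seen, and Kcnd2 lost its call without aMHC_Cre 2 or any heart without Cre (adjusted p 0.0504 to 0.066).

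**Figure D2:**
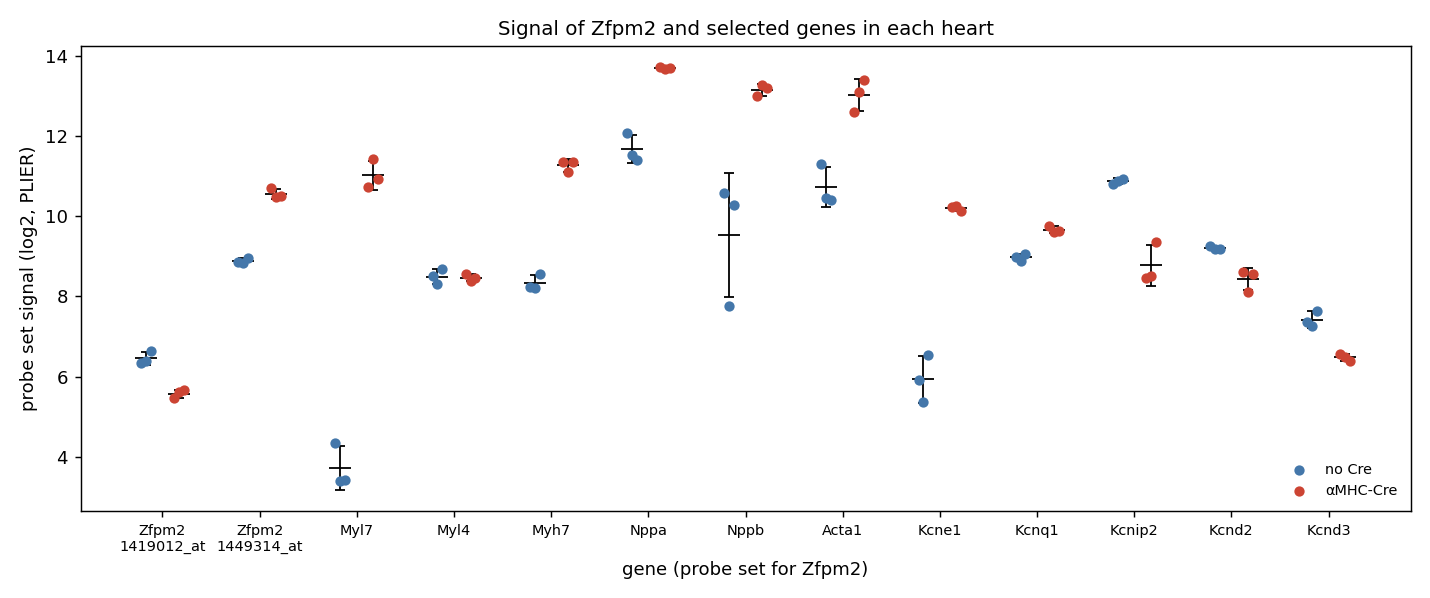
Each point is the log2 signal of 1 heart, blue without Cre and red with αMHC-Cre, and bars give the mean and SD of 3 hearts. The 2 Zfpm2 probe sets differ in opposite directions, Myl7 lies at 3.72 against 11.02 while Myl4 lies at 8.49 against 8.47, and Kcne1 and Kcnq1 are higher and Kcnip2, Kcnd2 and Kcnd3 lower with Cre.

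Fatty acid oxidation genes were lower with Cre in 5 of 31 cases and higher in 0 (14 lower adjusted over the list alone), with a median of -0.34. The β-oxidation enzyme genes Eci1 and Acaa2 fell by 0.74 ± 0.12 (SE) and 0.61 ± 0.11, the carnitine palmitoyltransferase gene Cpt2 by 0.66 ± 0.12 the fatty acid transporter gene Slc27a1 by 0.56 ± 0.12 and the electron transfer flavoprotein gene Etfb by 0.45 ± 0.11. The camera adjusted p was 1.1e-08, and the adjusted p = 0.46 with an estimated correlation. Of 28 respiratory chain genes, only Cox7a1 passed (0 adjusted over the list alone) and fell by 0.49 ± 0.11, with a list median of -0.10. That list had a camera adjusted p of 0.029, and adjusted p = 0.83 with an estimated correlation. Its call was also lost without no_Cre 1 (0.055), no_Cre 3 (0.051) or aMHC_Cre 1 (0.067) and with quantile normalization (0.085). Some members of the fatty acid oxidation and respiratory chain lists read near the array maxima of 13.97 to 14.00, such as Fabp3 at 13.71 and Sdhb at 13.32 without Cre. Differences may be compressed there. Of 18 glycolysis genes, Hk1 rose by 0.52 ± 0.12 and Hk2 fell by 0.77 ± 0.16 (3 and 4 adjusted over the list alone), and the list was not shifted (camera adjusted p 0.81). Another tested probe set differed by -0.83 for Cpt2 (adjusted p 0.051) and by -0.51 for Slc27a1 (0.073). The calls of Slc27a1, Etfb, Cox7a1 and Hk1 were lost whichever heart was left out (adjusted p 0.063 to 0.16). Those of Hk2, Acaa2 and Cpt2 were lost without aMHC_Cre 2 (0.12, 0.085 and 0.068), and Hk2 and Acaa2 lost theirs without other single hearts too.

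Genes of blood vessel growth went both ways. Of 43 tested, 3 rose and 3 fell (7 and 4 adjusted over the list alone), and the list was not shifted (camera adjusted p 0.31). Serpinf1, an inhibitor of angiogenesis, rose by 0.98 ± 0.13 (SE), Col18a1, the source of endostatin, by 0.57 ± 0.11, and Fgf18 by 1.00 ± 0.20. The growth factor genes Fgf9, Fgf16 and Fgf1 fell by 1.57 ± 0.25, 1.08 ± 0.18 and 0.57 ± 0.12. Vegfa was at 9.95 ± 0.18 (SD, n = 3) without Cre and 9.87 ± 0.26 with Cre, a difference of -0.08 ± 0.16 (SE, adjusted p 0.86) that ranged from -0.19 without aMHC_Cre 1 to 0.06 without aMHC_Cre 2. Fgf16 lost its call without aMHC_Cre 2 (adjusted p 0.057), and Col18a1 without no_Cre 1, no_Cre 2, aMHC_Cre 1 or aMHC_Cre 2 (0.054 to 0.087). Fgf1 lost its call without no_Cre 1, no_Cre 3, aMHC_Cre 2 or aMHC_Cre 3 (0.079 to 0.11), and Fgf18 without no_Cre 3, aMHC_Cre 1 or aMHC_Cre 3 (0.052 to 0.069). Of 22 hypoxia-induced genes, Ero1a rose by 1.09 ± 0.14 and Adm, which encodes adrenomedullin, by 1.13 ± 0.16 (4 higher and 1 lower adjusted over the list alone), and the list was not shifted (camera adjusted p 0.25). Fgf18, Fgf1 and Vegfa were singled out after their values had been seen.

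The remaining functional lists were not shifted by camera. None of 20 sarcomere genes passed, also adjusted over the list alone (camera adjusted p 0.92). Lmod2 differed by -0.41 ± 0.12 (SE, adjusted p 0.11) and Nebl by 0.34 ± 0.11 (0.14), and they passed in 3 and 4 of 20 alternatives. Myh6, singled out after its values had been seen and the gene whose promoter drives Cre, differed by -0.02 ± 0.11 (-0.05 without no_Cre 2 to 0.0022 without aMHC_Cre 2). Myh6 read 13.81 to 13.90 in all hearts, close to the array maxima of 13.97 to 14.00, as did several other members. Differences may be compressed there, so an unchanged level cannot be inferred. Of 25 apoptosis and p53 genes (0.39; 2 higher adjusted over the list alone), the survival gene Bcl2 rose by 2.07 ± 0.18 and the cell cycle inhibitor Cdkn1a by 1.44 ± 0.18. Of the 4 tested probe sets of Bcl2, 1 differed by 0.01 (adjusted p 0.98). Of 26 genes of the unfolded protein and integrated stress responses (0.14; 4 higher and 1 lower adjusted over the list alone), Psat1 rose by 1.35 ± 0.16, Nupr1 by 0.81 ± 0.15 and Asns by 0.69 ± 0.12. Of 28 cardiac transcription factors (0.59; 5 higher and 2 lower adjusted over the list alone), Zfpm1, the other Fog family gene, rose by 0.75 ± 0.12, Hey2 by 0.75 ± 0.16 and Nkx2-5 by 0.58 ± 0.12. Another tested probe set of Zfpm1 differed by 0.49 (adjusted p 0.18). Of 16 cell cycle genes (0.79), Cenpa fell by 1.08 ± 0.15 (1 lower adjusted over the list alone), with a median of 0.02, a mean of -0.03 and a downward test. No immediate early gene of 16 passed (0.79, with 1 lower adjusted over the list alone), with Ier3 at -0.60 ± 0.15 (adjusted p 0.054). Ier3 passed in 9 of 19 alternatives, at 0.044 without no_Cre 2 and at 0.010 where the limma adjusted p was lowest. Without aMHC_Cre 2 the calls of Asns (adjusted p 0.057), Nupr1 (0.076), Zfpm1 (0.051), Nkx2-5 (0.070) and Hey2 (0.14) were lost, the last 2 also without other single hearts.

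Lists of markers covered other cell types that the apex could hold. Of 23 endothelial markers only Vwf passed, with a rise of 1.12 ± 0.17 (SE; 3 higher adjusted over the list alone), and the list was not shifted (camera adjusted p 0.18, but 0.041 without aMHC_Cre 3). None passed among 11 pericyte and smooth muscle markers (0.33), where Acta2 differed by 0.80 ± 0.30 (0.49 without aMHC_Cre 3), or among 18 macrophage markers (0.38). Of the macrophage markers 14 were higher, with a median of 0.09, and Cd14 differed by -0.33 ± 0.14 and Cd68 by 0.22 ± 0.11. None passed among the tested markers, which were 2 of 12 listed for lymphocytes (0.92), 2 of 8 for adipocytes (0.78), 4 of 7 for erythroid cells (0.29) and 5 of 6 for platelets (0.63). Among them Cd8a differed by -0.09, Lep by -0.17, Hbb-b2 by 0.34 and Itgb3 by -0.21. The lymphocyte median was 0.0043 with a downward test, and Cd8a turned to 0.12 without no_Cre 2. Lep and Itgb3 were at -0.03 and -0.02 without no_Cre 3 and at -0.32 and -0.34 without no_Cre 1, and Hbb-b2 was at 0.21 without aMHC_Cre 1. Both tested epicardial markers rose, Aldh1a2, a retinoic acid-producing enzyme, by 1.64 ± 0.29 and Upk1b by 0.63 ± 0.15 (2 adjusted over the list alone). The other listed epicardial markers, of 10 in all, were too dim to test, so the list test rests on these 2 genes. The epicardial list had a camera adjusted p of 0.013, and adjusted p = 0.35 with an estimated correlation. None of 5 Schwann cell markers passed (2 higher adjusted over the list alone), with Pmp22 at 0.44 ± 0.12 (adjusted p 0.066). Pmp22 passed in 8 of 20 alternatives, with a limma adjusted p as low as 0.015. The Schwann cell list was nonetheless shifted upward by camera (adjusted p 0.019), and the adjusted p = 0.27 with an estimated correlation. That list also lost its call without aMHC_Cre 1 (0.067). The call of Upk1b was lost without each heart except no_Cre 3 (adjusted p 0.064 to 0.14).

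Of 6 tested atrial cardiomyocyte markers, Myl7 and Clu, the latter encoding clusterin, rose (2 adjusted over the list alone), Clu by 1.35 ± 0.13 (SE). Myl4, the atrial essential light chain, was at 8.49 ± 0.19 (SD, n = 3) without Cre and 8.47 ± 0.08 with Cre, a difference of -0.02 that ranged from -0.12 without no_Cre 2 to 0.07 without no_Cre 3. The atrial list had a camera adjusted p of 0.033, and adjusted p = 0.27 with an estimated correlation. Without Myl7, camera gave an unadjusted p of 0.28 for the other 5 genes. The call was lost without no_Cre 2 (adjusted p 0.059), no_Cre 3 (0.051) or aMHC_Cre 1 (0.067) and with quantile normalization (0.11). The Y-linked gene Uty differed by 0.27 ± 0.26 (SE) and Xist by -0.24 ± 0.23, neither passing, in these male hearts. Uty was at -0.05 without no_Cre 3, and Xist at 0.04 without aMHC_Cre 1.

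**Figure D3:**
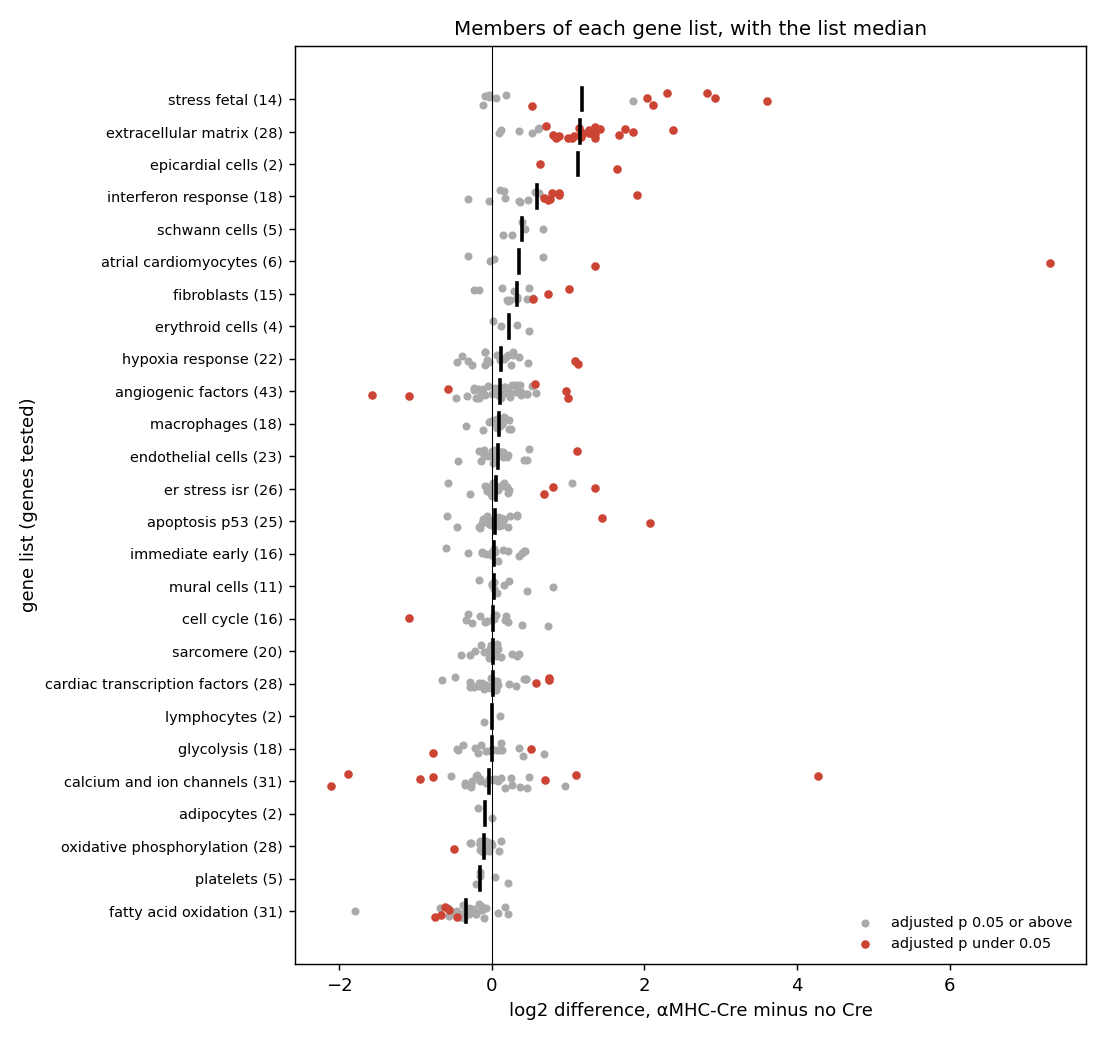
Each point is a tested member of 1 of 26 gene lists, with its log2 difference between hearts with and without Cre on the horizontal axis, in red at an adjusted p under 0.05. Black bars mark list medians, from 1.18 for stress genes and 1.15 for matrix genes to -0.34 for fatty acid oxidation genes, and the number tested stands in parentheses.

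In all, camera called 9 of the 26 lists, 7 upward and 2 downward, with a preset correlation of 0.01 between genes. None of them held with an estimated correlation, while fry, which asks whether a list's own genes move one way on balance, called 10. The hearts number 3 per group, which limits the precision of every difference (median SE 0.14).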

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

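The signals below come from probe sets left out of the main comparison as dim, and the rule that picked them (adjusted p under 0.05 in the fit of all probe sets, every heart without Cre under 4.48 and every heart with Cre above it) was set after such probe sets had been looked over, and was extended to genes with a tested probe set after Gabrb2 had been seen. The level of 4.48 is the highest value of the bacterial trpn control probe sets, taken as a reference level only. Since the rule asks for low signals without Cre, the sizes depend on the low end of the scale, and differences with 16 added to the unlogged signal are given beside them, without a test.

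For 6 genes with no tested probe set, the signal was higher with Cre. The C-type lectin gene Clec5a went from 3.13 ± 0.37 (SD, n = 3) to 5.96 ± 0.21, a difference of 2.83 (limma adjusted p 0.021). Plcxd2 also differed by 2.83 (0.048). The growth factor gene Nrg1, which encodes neuregulin, went from 3.62 ± 0.19 to 6.22 ± 0.08, a difference of 2.59 (0.0083). The follistatin-like gene Fstl3 differed by 1.96 (0.027), Dkk3, a member of the atrial list, by 1.67 (0.0083) and Clca3a1 by 1.56 (0.027). With 16 added, these 6 differences lay between 1.03 for Clca3a1 and 1.69 for Plcxd2.

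For 2 genes a dim probe set was higher although no tested probe set of the gene changed. Of Gabrb2, a GABA-A receptor subunit gene, 3 dim probe sets differed by 4.54, 4.29 and 4.26 (limma adjusted p 0.0083 to 0.023), or 2.69, 2.66 and 2.61 with 16 added, while its tested probe set differed by 0.08 ± 0.13 (SE). Of Vps11, 1 dim probe set differed by 1.54 (0.031, and 0.77 with 16 added), against -0.20 ± 0.12 and -0.19 ± 0.11 in its tested probe sets. A further 9 such probe sets belong to genes with a changed tested probe set.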

How the results depend on the processing

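Of 732 comparisons of 34 counts, lists and Zfpm2 values with an alternative, 628 stayed the same, 44 counts moved by over 1.5 times, 32 calls were lost, 7 were gained and 21 changed direction; where no cause is given, the cause was not tested. Each of the 1412 probe sets called in the main comparison kept its sign wherever a setting gave it a value, which was the case for 1045 with the 60% filter, 1411 with quantile normalization and all of them otherwise. Filters, variance settings, the replicate block and the way to represent a gene leave the difference of a probe set as it was. Only rescaling, offsets, array weights and left-out hearts could change a sign, for probe sets picked as changed in these same data. Of 67 named genes that changed, 22 were called under every alternative that gave a value for them (15 of these under all 20), 48 under every such alternative except no filter, and 0 reversed. The stricter filter or the choice of probe sets without a suffix left the others without some value. Dim signals limit the folds, since no offset holds them up, and 3 hearts per group limit the calls.

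Without a filter, 275 probe sets (226 higher, 49 lower) and 152 genes (130 and 22) changed. On the same probe sets 1833 changed with trend and robust variance settings and 1474 with 16 added, 2 settings chosen after the 275 was known. The share higher, 65.7%, was 82.2% without a filter, 76.2% without no_Cre 3 and 76.8% without aMHC_Cre 2. Without a filter, the epicardial list had an adjusted p of 0.0762 (0.0548 with trend and robust settings). The cell cycle list turned upward at 0.181 (0.230 with trend and robust settings, 0.190 with 16 added), and the lymphocyte list changed direction at 0.884 (0.932 and 0.969).

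Counts of lower probe sets and genes were 756 and 424 with trend and robust settings, and 407 genes with 64 added. At an adjusted p under 0.01, 529 probe sets (410 higher, 119 lower) and 321 genes (253 and 68) changed. At 0.10, 2220 probe sets (869 lower) and 1226 genes (449 lower) changed. The offsets were chosen after seeing the data.

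The dimmer Zfpm2 probe set passed at -0.89 with quantile normalization, -0.88 with the 40% filter and with trend and robust settings, -0.71 with 16 added and -0.45 with 64 added. With quantile normalization the respiratory chain list had an adjusted p of 0.0849 and the atrial list 0.115, and glycolysis changed direction (0.970). The atrial list had 0.0632 with array weights, which also turned the sarcomere list (0.955), and 0.0531 with the mean over probe sets. With probe sets without a suffix, the respiratory chain list had 0.186 and the atrial list 0.287, and the cell cycle (0.693) and erythroid (0.789) lists changed direction. With an estimated correlation the stress, matrix, interferon, fibroblast, atrial and Schwann cell lists had 0.271, fatty acid oxidation 0.460, respiratory chain 0.831 and epicardial 0.349. With fry the ion channel list changed direction (0.890) and the unfolded protein list passed (0.0372).

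With the replicate number as a block, 909 probe sets (252 lower) and 536 genes (144 lower) changed, and the atrial list had an adjusted p of 0.0625. In the fit of all probe sets with this block, the brighter Zfpm2 probe set lost its call at 1.68 (adjusted p 0.24), while in the fit without dim probe sets both were called (0.0039 for the brighter one and 0.018). The titles do not say whether the numbers stand for a pairing or a batch. Deviations of hearts with the same number correlated at -0.06, 0.21 and -0.19 across probe sets, and other pairs reached 0.27. As each deviation is taken from a mean of only 3 hearts, these values cannot exclude a pairing. The added poly-A control RNAs averaged 7.74 in no_Cre 1 and 7.47 in aMHC_Cre 1, and 6.56 and 6.02 for number 2. For number 3 they averaged 7.20 and 6.85, so the numbers ordered this control alike in both groups. A ribosomal RNA control had the same order, at 8.26, 7.50 and 7.51 without Cre and 8.19, 7.34 and 7.54 with Cre. So had the hybridisation controls, highest for number 1 (10.51 and 10.20) and lowest for number 2 (9.88 and 9.80). The array medians and the Gapdh and Actb measures were not ordered alike. A batch shared by hearts with the same number is therefore not excluded.

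Leaving out 1 heart at a time gave 600 to 1075 probe sets (461 to 803 higher, 139 to 390 lower) and 360 to 605 genes (286 to 461 and 74 to 215), with fewer hearts. The brighter Zfpm2 probe set ranged from 1.61 to 1.72. Adjusted p ranged from 0.0338 to 0.0674 for the respiratory chain, 0.00879 to 0.0674 for atrial, 0.0140 to 0.0674 for Schwann cell and 0.0408 to 0.735 for endothelial genes. Directions changed for lymphocyte (0.681 to 0.972), sarcomere (0.735 to 0.974), adipocyte (0.526 to 1.00), glycolysis (0.499 to 0.991) and immediate early genes (0.0980 to 1.00).

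Some genes picked by the naming rule that did not pass were called under alternatives. These were Ier3 in 9 of 19, Pmp22 in 8 of 20, Nebl in 4 of 20, Lmod2 in 3 of 20 and the smooth muscle marker Smtn in 1 of 19. Others changed sign. Retn was at -0.018 with quantile normalization, -0.00012 with median centring, -7.3e-05 with 64 added and -0.071 to 0.098 when single hearts were left out. Cd8a was at 0.022 with array weights (-0.23 to 0.12 without single hearts), Cd3e at -0.088 (-0.17 to 0.51) and Hbb-b2 at -0.12 with probe sets without a suffix. Without single hearts, Uty ranged from -0.050 to 0.45 and Xist from -0.49 to 0.036.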

Other observations

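The gene families in the first paragraph and all tests here were chosen after the results had been seen, except the counts over other splits of the hearts and the window of neighbouring genes, which were planned before their results were seen.

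Members of 5 further families were looked at without a test of the families as such (limma adjusted p per gene). Of 6 type IV collagen chains, the basement membrane collagens, 4 rose: Col4a3 by 1.66 ± 0.16 (SE), Col4a4 by 1.73 ± 0.18, Col4a5 by 0.77 ± 0.13 and Col4a6 by 0.93 ± 0.15 (adjusted p 0.00066 to 0.0095). The abundant chains Col4a1 and Col4a2 differed by 0.58 ± 0.16 and 0.37 ± 0.17 without passing, but passed at 0.76 and 0.57 without no_Cre 3 (adjusted p 0.019 and 0.046). Of 8 tested secreted Wnt inhibitors, Sost, Sfrp2 and Frzb rose, the last 2 by 2.16 ± 0.28 and 1.37 ± 0.16, and the others did not pass. Of 7 tested β-tubulin genes, Tubb2b rose by 2.51 ± 0.16 and Tubb2a by 1.32 ± 0.25, which lost its call without no_Cre 2 (0.058). Of 5 tested anoctamins, Ano3 rose by 4.43 ± 0.21 and Ano4 by 1.31 ± 0.19 while Ano10 fell by 2.24 ± 0.32. Of 2 tested neurofilament chains, Nefm rose by 4.82 ± 0.47 and Ina did not pass. Under quantile normalization or median centring, 1 sign changed in these families, that of Ano1 (0.01 to -0.0050 with quantile normalization).

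The Zfpm2 probe sets moved in opposite directions, -0.88 and 1.68. Among 244 genes with 2 or more changed probe sets in the fit without dim probe sets, Zfpm2 was the only one to do so, or 0.41%. Opposite changes were thus rare where both probe sets passed. Genes with 1 changed and 1 unchanged probe set, such as Sost (3.45 and -0.12), are not counted, so other disagreement of probe sets is not excluded. In the limma fit chosen beforehand for Zfpm2 the dimmer probe set did not pass (adjusted p 0.068). A candidate explanation is that 1 probe set lies in the deleted part of the gene and the other in a retained part. It stays open, since 0 of the probe sets of Zfpm2 had a position in the tables used, and higher transcription of the recombined gene was not tested.

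Myl7 rose from a low signal while Myl4 did not pass. Atrial tissue in the samples with Cre would bring other atrial transcripts, yet the highest upper 95% limit among the differences of Sln, Myl4 and Bmp10, picked after their values had been seen, was 1.30 on the log2 scale, under a bound of 2 set when these values were roughly known. The mean of Sln (2.85 and 3.28 in the 2 groups) stayed under the reference level of 4.48 with Cre, although atrial tissue should lift it well above background. No atrial sample shows how strongly its probe set would read, and Bmp10 (5.37 and 4.85) is dim and weighs little. Myl4 (-0.02, 95% interval -0.35 to 0.31) argues against atrial tissue. Of the atrial list, Clu rose by 1.35 (limma adjusted p 0.00075) and the dim Dkk3 by 1.67 (0.0083), so atrial tissue is not excluded. The size of 7.30 depends on the low signal without Cre, but the rise does not rest on it alone, since the difference was 6.15 with 16 and still 4.78 with 64 added to the unlogged signal. An effect of Cre itself rather than of the deletion cannot be told apart, as 0 hearts had Cre and no floxed allele, and loss of Fog2 may be the cause.

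Extracellular matrix genes rose by a median of 1.15 (95% bootstrap interval over genes 0.88 to 1.28). A lower share of cardiomyocytes would raise markers of every other cell type alike. The 52 endothelial, mural and macrophage markers had a median of 0.074 (0.03 to 0.13), which argues against it as the source of the whole rise. Smaller marker lists were mixed, with medians of 1.14 for 2 epicardial, 0.40 for 5 Schwann cell and 0.23 for 4 erythroid markers. Platelet, adipocyte and lymphocyte markers had medians of -0.15, -0.09 and 0.0043. A smaller fall in the share is therefore not excluded. More fibroblasts with unchanged expression per cell would raise fibroblast markers as much as matrix genes. The fibroblast markers had a median of 0.33 (0.21 to 0.49), too little for the whole rise. These intervals are taken over genes and leave out variation between hearts. A change of state of the matrix-producing cells may remain, as a hypothesis that these data do not test, and Cre and the deletion cannot be told apart here either.

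The 6 hearts can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For changed probe sets, 1 of the 10 splits, the real one, gave as many as 1412, and the highest of the others gave 0 (up to 2206 at an unadjusted limma p under 0.05, against 4771). For gene lists called by camera, 1 of 10 gave as many as 9, and the highest of the others gave 8. Each other split still sets 2 hearts of a group against the third, so it can keep part of a group difference. In the other splits the matrix list was called in 4 of 9 and the fatty acid oxidation list in 5 of 9, and the fibroblast list reached a lower adjusted p (8.1e-05) than in the real split (0.00021). No member of any list passed in another split, which follows from the 0 changed probe sets there. Groups that mix hearts with and without Cre also carry that difference in their spread, which lowers the number of calls.

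A segment of chromosome next to an inserted transgene may carry many changed genes. The highest number of changed genes in a window of 20 neighbouring tested genes was 7, against a median of 6 for the highest window in 1000 shuffled orders (permutation p = 0.35). This gave no sign of such a segment at that window size, but other sizes were not tested, so a shorter segment is not excluded. Pairs of directly neighbouring tested genes that changed the same way numbered 59, against a mean of 28.1 in shuffled orders (permutation p = 0.001, the smallest that 1000 orders can give). Of these pairs, 48 were higher and 45 had symbols that differ in their first 3 letters, as with Meox1 and Sost. Among the 59 are Nppb and Nppa, Col3a1 and Col5a2, Col4a4 and Col4a3, and Vldlr and Kcnv2. Some pairs join into longer runs, such as Col6a3, Rab17, Lrrfip1 and Ramp1 on chromosome 1, which rose by 1.15, 0.76, 0.66 and 1.42.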
